A study of Mus musculus with 6 samples.

How the data were processed

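RNA abundance was measured on Affymetrix whole-transcript arrays in 6 samples of E14 cells, a mouse embryonic stem cell line. The sample titles put 3 arrays in a control group and 3 in a Tdg knockdown group, and number the arrays 1 to 3 within each. Nothing in the labels says that the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

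The deposited values are log2 signals, 1 per probe set and array, rounded to 2 decimals and between 2.26 and 14.03. They were made with Affymetrix Expression Console, per the submitters' processing notes. The version, the summarisation and the normalization between arrays are not given in the sources used here. The log2 scale was taken from the range of the deposited values, and the column medians lay between 7.41 and 7.48. Biotin-labelled target was prepared from total RNA, per the labels' protocols. No further normalization was applied for the main results.

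The table has 35557 rows. The platform annotation lists 1 gene for 21789 of them, several genes for 1621 and none for 12147. Of the rows with 1 gene, 21698 were matched by gene identifier to the RefSeq table of assembly GRCm38.p6, which was used only for names and for which genes neighbour each other. Rows listing several genes or none were not named. For a gene with several rows the one with the highest mean over the 6 arrays was taken, which left 19938 named genes. Tdg has no row of its own: 4 rows list it together with the pseudogene Tdg-ps2. Their mean per array was fitted beside the named genes, is reported as Tdg or Tdg-ps2, and is not in the count of genes.

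Knockdown was compared with control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided), with Benjamini-Hochberg adjustment over the named genes and a threshold of 0.05. Fold changes are knockdown minus control on the log2 scale. For Tdg an exact two-sided permutation test was also made, whose smallest possible p with 3 arrays against 3 is 0.1. The 29 gene lists were fixed before the data were examined and were tested with camera at a preset correlation of 0.01, with adjustment over the lists. List members under older symbols were matched through synonyms only where the old symbol is no longer in use and points to 1 gene. Members not measured by a row of their own were not analysed here. The count of members adjusted over the list alone is given beside that over all genes.

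The genes named in the text follow a rule also set at that stage. It takes Tdg, the 12 genes with the largest increase and the 12 with the largest decrease among those past the threshold whose groups do not overlap, leaving out predicted models, microRNAs and small nucleolar RNAs. From each list it takes up to 4 members past the threshold in each direction, or the 2 with the smallest p where none passed. It also takes Kdm2b, Tet1, Tet2 and Tet3, which the labels name. Genes named beyond this rule are said to have been chosen after their values were seen.

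The replicate numbers in the titles were checked for pairing, since no label says what equal numbers share. The deviations from the group means of arrays with the same number correlated at 0.61, 0.23 and 0.70 across genes, and 5 of the 6 arrays correlated best with their own number in the other group. The exception was knockdown replicate 2, at 0.44 with control replicate 1. By the criterion used, a correlation over 0.1 in every pair, the numbers were treated as pairing the samples. With so few arrays per group few other matchings exist, so the numbered matching can fit best by chance. The criterion therefore does not establish that the samples are paired, and the blocked values hold only if they are. The main model has no block, and the value with the replicate number as a block is given wherever it changes a call or moves a count by more than 1.5 times.

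The alternatives were the replicate block, quantile normalization, centring each array on its median, leaving out the third of rows with the lowest mean level, a trended and robust prior, array weights, the mean of a gene's rows, testing all rows, a minimum fold change of 1.5 or 2, treat against a 1.2-fold change, and leaving out each array in turn. For the lists, camera with an estimated correlation and fry were added. Leaving out both arrays numbered 3 was chosen after seeing the data. For the random gene lists used in the closing section, 10000 lists of the same size were drawn, matched on mean level.

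The procedure was tested on simulated data with the levels and spreads of this comparison, in 5 runs over 19938 genes with 200 changed in each. It recovered 51.2% of genes changed by 0.5 on the log2 scale, 84.8% at 1, 99.2% at 2 and 99.6% at 3, and 3.7% of its calls were false. A list shifted by 0.3 was called in 5 of 5 runs, and 0 of 95 unshifted lists were. The simulated noise was drawn independently for each gene and array, without an array-wide shift or pairs. These rates therefore do not cover correlated genes, and they do not show how often list calls in these arrays are false. For arrays the number of replicates, 3 per group, limits the precision. Figures were drawn with matplotlib 3.10.9.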

Results

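Gene expression was compared between control E14 mouse embryonic stem cells and cells in which Tdg was knocked down. Tdg encodes thymine DNA glycosylase, a base excision repair enzyme that removes thymine from mismatches and some, not all, of the oxidised cytosines that TET enzymes make. The series title places the comparison in a study of cytosine oxidation by TET and TDG. Cells were grown on 0.1% gelatin in 15% serum with LIF at 1000 units/ml, and were infected with lentiviral vectors at a multiplicity of infection of 10. Puromycin at 2 ug/ml was added 48 h later. Each group had 3 arrays.

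The 6 arrays correlated at 0.975 to 0.996 with each other. The first principal component held 58.6% of the variance and set knockdown replicate 3, at 31.0, apart from the other 5 arrays, which lay between -17.5 and 5.2. The second held 22.1% and separated the groups, with controls at 4.6, 8.0 and 12.7 and knockdown arrays at -12.0, -11.9 and -1.5. In knockdown replicate 3 the 1027 olfactory receptor genes, which are mostly silent in these cells, had a median deviation of 0.18 from the mean over the arrays, and 347 Zfp genes one of -0.13.

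Tdg signal fell by 3.03 on the log2 scale, from 11.14 ± 0.05 in control to 8.11 ± 0.16 in knockdown cells (SD, n = 3 each), which leaves 12.2% of the control level. The standard error was 0.09 and the adjusted p was 8.79e-05, and in an exact permutation test the p was 0.1, the smallest that 3 against 3 allows. The 4 rows behind this mean, which the annotation shares between Tdg and its pseudogene Tdg-ps2, ran from -2.94 to -3.13. The extraction protocol speaks of Kdm2b knockdown cells, while the titles and the series design name Tdg. Kdm2b, a histone demethylase, differed by 0.10 (SE 0.08, adjusted p 0.694). The oxidising enzymes showed 0.01 for Tet1 (adjusted p 0.976), 0.14 for Tet2 (0.665) and -0.12 for Tet3 (0.609), none past the threshold.

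**Figure D1:**
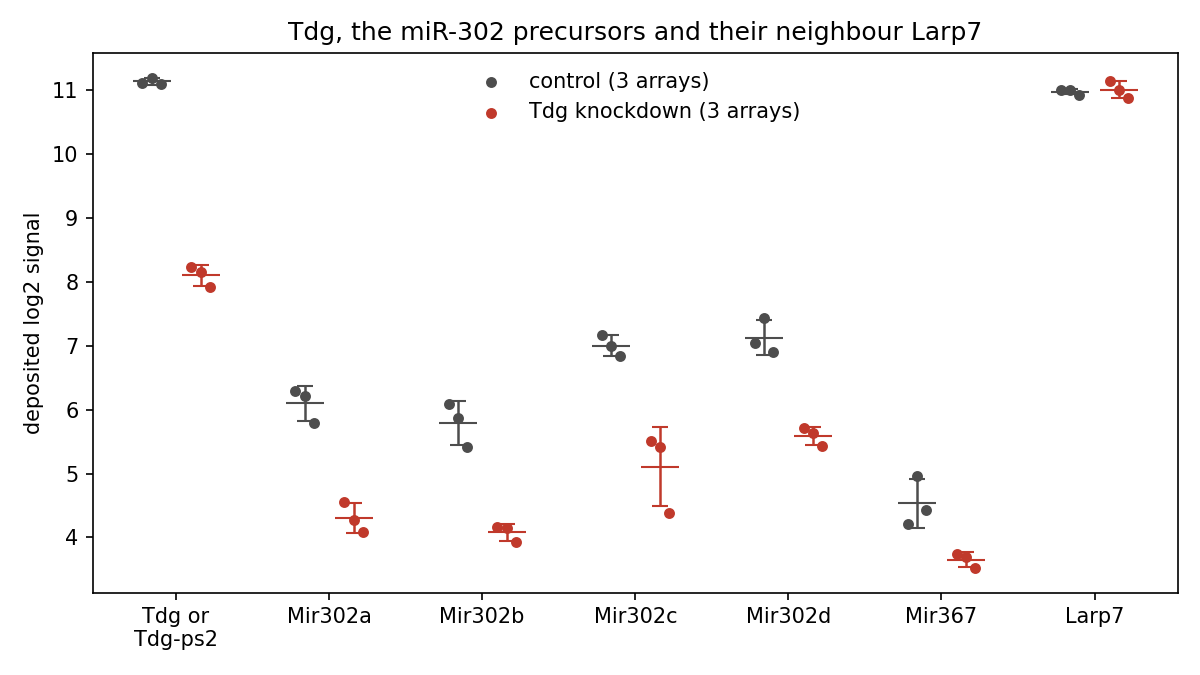
Deposited log2 signal per array (vertical axis) of Tdg or Tdg-ps2 (mean of 4 rows), 5 microRNA precursors of the miR-302 cluster and the neighbouring gene Larp7, with points for single arrays and bars for the mean and SD of 3 control (grey) and 3 Tdg knockdown (red) arrays. Tdg fell by 3.03 and the 4 miR-302 precursors changed by -1.53 to -1.90, while Larp7 differed by 0.03.

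Among 19938 named genes, 48 rose and 110 fell in knockdown cells. The largest increases were in Nlrc4, an inflammasome sensor (0.95 ± 0.10, log2 fold change ± SE), Pax6, a transcription factor of eye and neural development (0.93 ± 0.09), and the immediate early transcription factors Egr1 (0.84 ± 0.06) and Fos (0.84 ± 0.12). They were followed by the guidance cue Ntn1 (0.81), the helix-loop-helix inhibitor Id3 (0.80), the zona pellucida glycoprotein Zp3 (0.79), the mitochondrial serine transporter Sfxn1 (0.77), Tdpoz3 (0.73), the hedgehog-binding protein Hhip (0.71), Tdpoz2 (0.66) and the G protein subunit Gna14 (0.65). Leaving out microRNAs, the largest decreases were in the matrix glycoprotein gene Efemp1 (-1.11 ± 0.11), the guanylate-binding protein gene Gbp2b (-1.06 ± 0.06), the growth hormone receptor Ghr (-1.04 ± 0.10) and the kinase Nuak1 (2.00-fold lower, SE 0.09 on the log2 scale). Then came Trim67 (-0.94), the annexin Anxa3 (-0.93), the hyaluronan synthase Has2 (-0.93), Kctd12b (-0.91), the matrix protein Thbs1 (-0.90), the phosphatase subunit Ppp4r4 (-0.89), the semaphorin Sema3c (-0.89) and the metal transporter Slc39a8 (-0.89). Tdpoz2 and Tdpoz3 belong to a family of near-identical copies, so signal between copies is uncertain.

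The adjusted p of these 24 genes lay between 0.00773 and 0.0462. All 158 called genes had groups that did not overlap, as did 3780 of all genes (19%, against 10% by chance). The median size of a called change was 0.56, and 8 genes changed by at least 2-fold, all lower. At an unadjusted p under 0.05 there were 2494 genes, where 997 are expected by chance. With the replicate number as a block 614 genes passed, 214 higher and 400 lower, among them all 158 in the same direction. The count rests on few arrays: limma called 0 genes without control replicate 1, control replicate 2 or knockdown replicate 1 (1682, 1510 and 1958 at an unadjusted p under 0.05), 15 without control replicate 3, 4 without knockdown replicate 2 and 291 without knockdown replicate 3.

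**Figure D2:**
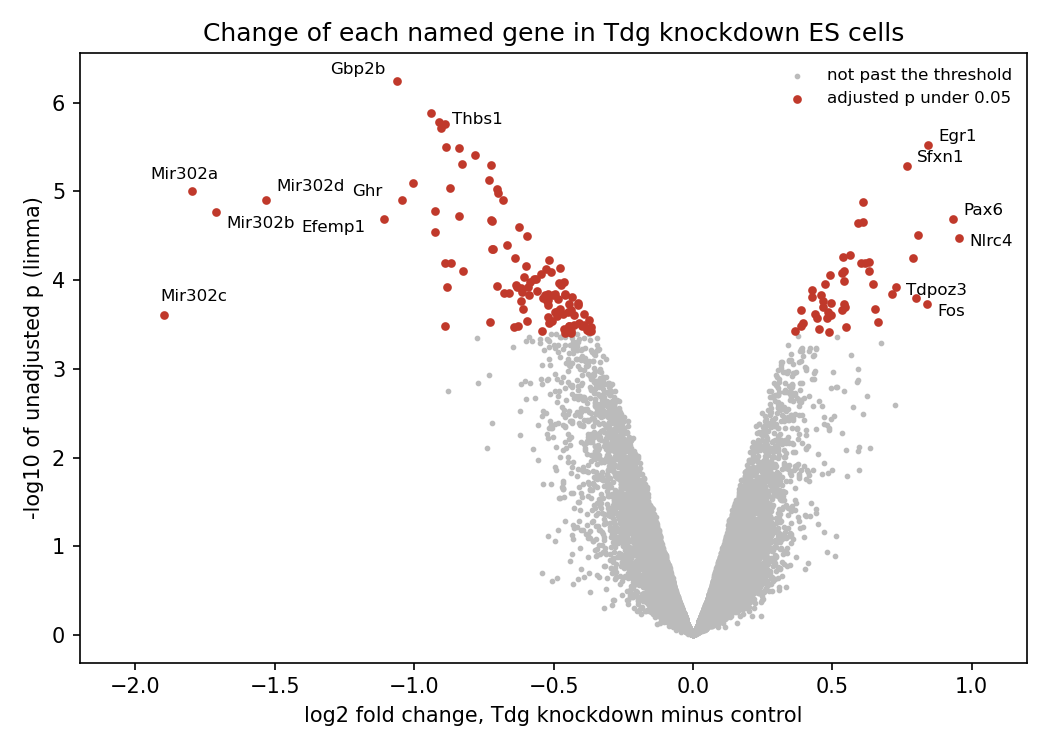
Log2 fold change of each named gene (horizontal axis, Tdg knockdown minus control) against -log10 of its unadjusted p from limma (vertical axis), with genes past the threshold in red and all others in grey. The 4 miR-302 precursors lie farthest to the left, between -1.53 and -1.90, and the largest increase is that of Nlrc4, at 0.95.

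The 5 called genes that the naming rule leaves out were 1 predicted model, I830077J02Rik (0.44 ± 0.07), and 4 microRNA precursors, all named after their values were seen. The microRNAs were Mir302a to Mir302d, 4 precursors of the miR-302 cluster. Their rows were dim, with control means of 5.79 to 7.12 against array medians of 7.41 to 7.48. All 4 fell, with log2 fold changes of -1.80 for Mir302a (SE 0.16), -1.71 for Mir302b (SE 0.17), -1.90 for Mir302c (SE 0.28) and -1.53 for Mir302d (SE 0.14), with adjusted p from 0.0115 to 0.0402. Signal over background was not analysed here, so these are changes of measured signal. Mir367 of the same cluster differed by -0.88 (SE 0.18, adjusted p 0.0919, or 0.0382 with the replicate block). Larp7, which neighbours the cluster in GRCm38.p6, differed by 0.03 (adjusted p 0.914). The calls of Mir302a, Mir302b and Mir302d were lost without control replicate 1, control replicate 2, knockdown replicate 1 or knockdown replicate 2 (adjusted p 0.0631 to 0.103), and that of Mir302c without any array but knockdown replicate 3 (adjusted p 0.0993 to 0.219). With all rows tested all 4 calls were lost (adjusted p 0.0726 to 0.135), and in the refits with lost calls the fold changes were -1.38 to -2.10. In the setting without the third of rows with the lowest mean level, all 4 were left out and not tested.

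Genes of the 2-cell-like state, a rare state of embryonic stem cell cultures with transcripts of the early embryo, were called higher as a list. The 13 measured members had a median log2 fold change of 0.39, and each lay above 0 (camera, adjusted p 6.24e-12 at the preset correlation, but adjusted p = 0.927 with an estimated correlation). Of these, 5 rose and 8 did not pass: Tdpoz3 (0.73), Usp17lb (0.49), Usp17lc (0.43), Tcstv3 (0.39) and Ubtfl1 (0.45), the last named after its values were seen. Adjusted over the list alone 10 rose, and with the replicate block 9 did. Members of the Tdpoz and Usp17l families share near-identical sequence and are uncertain one by one.

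Neuroectoderm genes were also called higher as a list (median 0.09 over 23 members, adjusted p 0.048), a call lost with an estimated correlation (adjusted p = 0.927). The list had Pax6 (0.93) past the threshold, 4 higher and 2 lower adjusted over the list alone, and 4 higher and 1 lower with the replicate block. The 2 lower, named after their values were seen, were Nes (-0.60, adjusted p 0.0845, blocked 0.0246) and Neurod1 (-0.48, 0.195, blocked 0.0572). The call of the neuroectoderm list was lost without knockdown replicate 3 (median 0.02, adjusted p 0.601) and without control replicate 1 (0.05, adjusted p 0.121). Primitive and visceral endoderm genes were called lower as a list (median -0.05 over 31 members, adjusted p 0.036, but adjusted p = 0.927 with an estimated correlation). None passed alone, 2 were lower adjusted over the list alone and 3 with the replicate block, and the smallest p were those of Hnf4a (-0.46, adjusted p 0.0673, blocked 0.036) and Lamb1 (-0.34, adjusted p 0.0842, blocked 0.0474). The call was lost without control replicate 3 (median -0.01, adjusted p 0.0637), knockdown replicate 1 (-0.03, 0.0987) or knockdown replicate 2 (-0.02, 0.157).

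Targets of p53 and genes of glycolysis and hypoxia were called slightly lower as lists. The 29 p53 targets had a median of -0.06 (adjusted p 0.0267, but adjusted p = 0.927 with an estimated correlation) with none past the threshold, 1 lower adjusted over the list alone and 1 with the block. Trp53inp1 showed -0.31 (adjusted p 0.065, blocked 0.0403) and the detoxifying hydrolase gene Ephx1 -0.30 (0.132). The 33 glycolysis and hypoxia genes had a median of -0.06 (adjusted p 0.0298, but adjusted p = 0.927 with an estimated correlation), none past the threshold, 4 lower and 1 higher adjusted over the list alone, and 2 lower with the block. Pfkm, a phosphofructokinase, showed -0.34 (adjusted p 0.0575, blocked 0.0382) and the angiogenic factor gene Vegfa -0.36 (0.0786, blocked 0.0336). Without knockdown replicate 3 both calls were lost (adjusted p 0.247 and 0.185), and without control replicate 1 the second was lost too (0.0978).

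**Figure D3:**
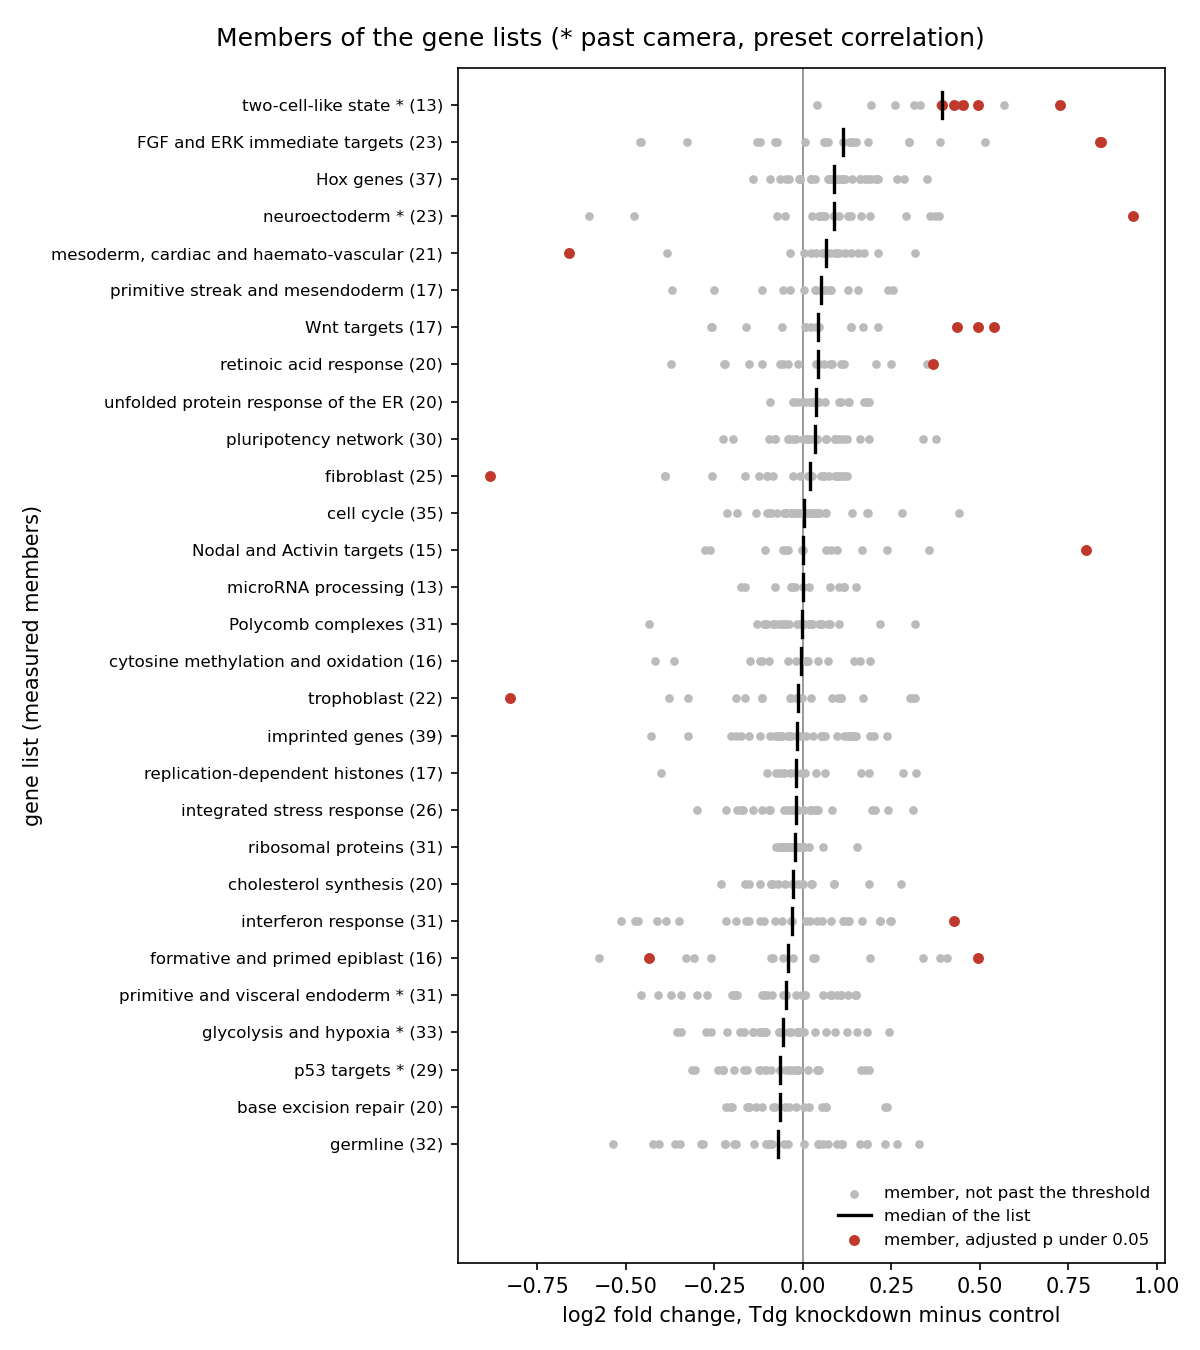
Log2 fold change (horizontal axis, Tdg knockdown minus control) of the measured members of 29 gene lists (vertical axis, number of members in parentheses), with red points for members past the threshold, grey points for the others, a black bar for the list's median and a star for lists past camera at the preset correlation. The 2-cell-like list has the highest median, 0.39, and all other medians lie between -0.07 and 0.11.

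The other 24 lists did not pass. The 20 base excision repair genes had a median of -0.07 (camera adjusted p 0.178) and none past the threshold, also adjusted over the list alone. The flap endonuclease gene Fen1 showed 0.23 (adjusted p 0.162) and the glycosylase gene Mpg -0.22 (0.222). Among 16 genes of cytosine methylation and oxidation the median was -0.01 (0.398), with none past the threshold and 2 lower adjusted over the list alone or with the block. These were Apobec1 (-0.36, adjusted p 0.0828, blocked 0.0422) and Gadd45b (-0.42, adjusted p 0.117, blocked 0.0368). The 39 imprinted genes had a median of -0.02 (0.743), with 0 past the threshold in any of these counts, and values of -0.32 for Sgce and 0.24 for Impact. The 32 germline genes had a median of -0.07 (0.132), with none past, 5 lower and 1 higher adjusted over the list alone and 3 lower with the block. Stag3 (-0.42, adjusted p 0.0563, blocked 0.0377) and Tdrkh (-0.41, 0.0736, blocked 0.0355) had the smallest p. The 31 Polycomb genes had a median of 0.00 (0.725), none past, 1 lower adjusted over the list alone, and 1 higher and 1 lower with the block. Pcgf5 showed -0.43 (adjusted p 0.0871, blocked 0.0355) and Scmh1 0.32 (0.128, blocked 0.0437).

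The 30 pluripotency genes had a median of 0.04 (camera adjusted p 0.226), none past the threshold, and 2 higher adjusted over the list alone or with the block: Nr0b1 (0.38, adjusted p 0.052, blocked 0.0306) and Gbx2 (0.34, 0.0563, blocked 0.0369). Of 16 formative and primed epiblast genes (median -0.04, 0.725), the Wnt effector Lef1 rose (0.49) and the claudin gene Cldn6 fell (-0.43). Adjusted over the list alone 5 were higher and 5 lower, and with the block 3 and 2. The 17 primitive streak genes had a median of 0.05 (0.904) and none past, with 1 lower adjusted over the list alone or with the block, Wnt3 (-0.37, adjusted p 0.098, blocked 0.0395), while Cdx4 showed -0.25 (0.213). Of 21 mesoderm, cardiac and haemato-vascular genes (median 0.07, 0.34) the cardiac factor gene Tbx20 fell (-0.66), 2 were lower adjusted over the list alone and 2 with the block. Of 22 trophoblast genes (median -0.01, 0.43) the keratin gene Krt19 fell (-0.83), 3 were lower adjusted over the list alone, and with the block 3 were lower and 1 higher. Of 25 fibroblast genes the actin-binding Tagln fell (-0.88), 4 were lower adjusted over the list alone and 3 with the block. That list had a median of 0.02, a mean of -0.06 and a test pointing down (0.178). The 37 Hox genes had a median of 0.09 (0.0556), which passed with the block (0.0335), and -0.02 without knockdown replicate 3. With an estimated correlation and no block the list had an adjusted p = 0.927. No Hox gene passed in any count, and Hoxd1 showed 0.27 (adjusted p 0.168) and Hoxb1 0.35 (0.245).

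In the signalling lists, Egr1 (0.84) and Fos (0.84) rose among 23 immediate targets of FGF and ERK (median 0.11, camera adjusted p 0.0535), 6 were higher and 3 lower adjusted over the list alone, and 5 higher and 2 lower with the block. Of 17 Wnt targets (median 0.04, 0.144) 3 rose: the Wnt-inactivating enzyme gene Notum (0.54), Lef1 (0.49) and the cyclin gene Ccnd2 (0.44). Adjusted over the list alone 4 were higher and 2 lower. Of 15 measured members of the list of Nodal and Activin targets (median 0.00, 0.557) Id3 rose (0.80). Which pathway raised Id3 was not tested, and its place in this list does not show it. In that list 2 were higher and 2 lower adjusted over the list alone, against 2 higher with the block. Of 20 retinoic acid response genes (median 0.04, 0.838) the receptor gene Rarg rose (0.37), with 1 higher and 1 lower adjusted over the list alone or with the block. Of 31 interferon response genes (median -0.03, 0.319) the RNA sensor gene Ddx58 rose (0.43), 1 was higher and 5 lower adjusted over the list alone, and 1 higher and 4 lower with the block.

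Stress, growth and housekeeping lists held no called gene. The 26 integrated stress response genes had a median of -0.02 (camera adjusted p 0.399), 1 higher adjusted over the list alone, and 1 higher and 1 lower with the block, Ppp1r15a (0.31, adjusted p 0.093, blocked 0.0423) and Pck2 (-0.30, 0.138, blocked 0.0452). The 35 cell cycle genes had a median of 0.00 (0.904) and 1 higher with the block, Ccne2 (0.44, adjusted p 0.139, blocked 0.0368), beside Mcm3 at -0.21 (0.196). The 17 replication-dependent histone genes had a median of -0.02, a mean of 0.01 and a test pointing up (0.743), with 1 higher with the block, H2ac1 (0.32, adjusted p 0.121, blocked 0.0392), and H2bc4 at 0.28 (0.257). In the last 4 lists 0 members passed in any count. The unfolded protein response of the ER had a median of 0.04 over 20 genes (0.0954), with Xbp1 at 0.19 and Hspa5 at 0.18. Cholesterol synthesis had -0.03 over 20 genes (0.398), with Tm7sf2 at -0.23 and Ebp at 0.28. MicroRNA processing had 0.00 over 13 genes (0.904), with Ago4 at -0.16 and Drosha at 0.15. Ribosomal proteins had -0.02 over 31 genes (0.325), with Rpl30 at 0.15 and Rpl22 at -0.08.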

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

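Of the tests below, those of the 2-cell-like members outside the families and of miR-302 without knockdown replicate 3 were chosen only after the results were seen. One signal lay outside the named genes: with all rows tested, probe set 10341592, for which the annotation used here lists no gene, was the only 1 of 12147 such rows past the threshold. It was 1.10 higher in knockdown cells (SE 0.09, adjusted p 0.0401, or 0.127 with the replicate block), with 5.80, 5.81 and 5.91 in the knockdown arrays against 4.80, 4.82 and 4.59 in the controls. No outlier test was made within the groups, which have 3 arrays each.

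The 158 genes called between knockdown and control stand against a highest count of 0 among the other splits of the 6 arrays, and 1 of the 10 splits, the real one, gave as many. With the replicate block, 614 genes stand against 0 in the other splits that part all pairs, and 1 of the 4 such splits gave as many. Both sets of splits are too few for a share under 0.05.

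Genes of the 2-cell-like state were higher in all 3 knockdown arrays, with list medians of 0.43, 0.48 and 0.36 against the control mean. Signal shared between near-identical copies is argued against by the 6 members outside the Usp17l, Tdpoz and Tcstv families, whose median was 0.41, at percentile 100 among 10000 random gene lists of like level. The array-wide shift of knockdown replicate 3 is argued against by a median of 0.44 without that array. The 24 rows that list several genes, many near-identical to each other, had a median of 0.42 and all lay above 0. None passed over all 35557 rows, a larger number of tests than for the named genes (lowest adjusted p 0.111, blocked 0.114). The rows of Zscan4, a defining marker of this state, showed only 0.13 to 0.17 (adjusted p 0.614 to 0.698). They were bright, at 12.61 to 13.27, where the highest signals per array were 13.97 to 14.03. Whether this limits their change was not tested. A larger share of cells in this state, or higher expression in all cells, may underlie the pattern; the effect of Tdg loss itself was not separated from an off-target effect of the vector.

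The 4 miR-302 precursors were lower in each knockdown array, by medians of -1.52, -1.61 and -1.94. Without knockdown replicate 3 their median was -1.59, which argues against the shift of that array. No knockdown value reached a control value, but this already held with all arrays, so leaving out an array could not change it. The 182 other microRNA rows of like level had a median of 0.04. Signal over background was not analysed, so rows with no signal to lose are not told apart among them. A general loss of signal in short, dim rows therefore stays open. Lower transcription or faster processing of the precursor could each give this pattern, and the 0.03 of Larp7 does not tell them apart. Neither was tested, and an off-target effect of the vector stays open.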

How the results depend on the processing

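The decrease of Tdg stayed past the threshold in all 15 alternatives, at -2.94 to -3.10. The count of 158 genes became 614 with the replicate block, 444 with the dimmest rows left out (the third with the lowest mean level), 446 with a trended and robust prior, 8947 with array weights (which did not converge, with weights from 0.132 to 8.56), 17 with all rows tested, 75 and 8 at a minimum of 1.5-fold and 2-fold, and 14 with treat. Leaving out 1 array gave 0 to 291 genes. Fewer arrays, more rows tested or a size minimum account for part of this by construction; otherwise the cause was not tested. The other counts were 197 (quantile normalization), 118 (median centring), 157 (mean of rows) and 112 (both arrays numbered 3 left out, chosen after seeing the data). All 158 genes kept their direction and an unadjusted p under 0.05 in each setting that tested them. With the dimmest rows left out 142 were tested. The groups of all 158 did not overlap, so leaving out arrays could not change a direction. Nor could the replicate block, which leaves each fold change as it is. These genes were also chosen for a small p in the same arrays, so this is no independent evidence. Of the lists, 5 passed, against 3 with the mean of rows, 8 with all rows, 3 to 7 with 1 array left out, 0 with an estimated correlation and 0 with fry (1 and 3 at an unadjusted p under 0.05). The 2-cell-like list passed in all 15 refits, with medians of 0.38 to 0.44, though not with an estimated correlation or fry (adjusted p 0.0831). Among single genes and lists 1237 values under alternatives were counted as staying on their side of the threshold. A further 261 were no longer past it, 120 came past it, 37 not past it were counted as changed in sign, and 0 called values reversed. The 37 do not hold every change of sign. The Hox median of -0.01 with array weights was counted among the 1237. Of 15 refits the call held in 11 for the primitive and visceral endoderm list, 9 for neuroectoderm, 12 for p53 targets and 10 for glycolysis and hypoxia, while the Hox and the FGF and ERK lists, not called, came past the threshold in 7 each. With the replicate block no list call changed but that of the Hox genes. Signal over background was not analysed here, so dim rows have no detection limit.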

Other observations

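The tests in this part that were chosen only after the results were seen are both gene lists, drawn up once the called genes were known and so no independent evidence of their direction, and the test of fibroblast genes. These lists cover programmes of cell shape and adhesion. Of 22 measured targets of YAP and TEAD, the effectors of Hippo signalling, 6 fell and 0 rose: Ccn1 (-0.73), Igfbp3 (-0.72), Tgfb2 (-0.51), Ankrd1 (-0.51), Amotl2 (-0.48) and Ptpn14 (-0.48). Ccn2, another widely used target, differed by -0.09 (adjusted p 0.616). Of 25 measured SRF targets and contractile genes 5 fell and 0 rose: Tagln (-0.88), Cald1 (-0.70), Tpm1 (-0.70), Cnn1 (-0.62) and Csrp1 (-0.47). The list leaves out Egr1 and Fos, immediate early genes that SRF also controls. Both rose (0.84 each), so the count of 0 holds for the list's members only. Actb differed by 0.01 and Srf by 0.09, neither past the threshold. With the replicate block 8 and 10 members fell. The list medians were -0.16 and -0.23, and camera gave an unadjusted p of 5.85e-10 and 2.32e-11, or 0.0257 and 0.0158 with an estimated correlation.

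Over the 47 members of both lists the median was -0.19. Fewer fibroblast-like cells stay open: 23 fibroblast genes outside the contractile list had a median of 0.02, but they went both ways, and the 6 brighter than the median gene had one of -0.17, with -0.39 for Mmp2 (adjusted p 0.052, blocked 0.0355) and -0.39 for Timp3 (0.166, blocked 0.0368). For the array-wide shift of knockdown replicate 3 the bounds of -0.1 and -0.2 set beforehand did not decide. Without that array the median was -0.16, between them. The medians were -0.20, -0.17 and -0.26 in knockdown replicates 1, 2 and 3, against 0.00 to 0.01 in the controls. For these list members, the values in knockdown replicates 1 and 2 argue against a shift confined to replicate 3 as the only source. The 36 members that did not pass had a median of -0.13, at percentile 0 among 10000 random lists of genes not past the threshold, but 25 lay below 0 and 11 above. Some were near misses that passed with the replicate block (Cnn2, adjusted p 0.054, blocked 0.0283, and Lats2, 0.0575, blocked 0.0417). The lists were also drawn up from called genes, so the median of the 36 does not settle whether the decrease is wider. Lower YAP and SRF activity may underlie the pattern, as a hypothesis, although Egr1 and Fos, which SRF also controls, rose. Cell density and attachment, which also act on genes of both lists, were not tested.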
